A study of Mus musculus with 8 samples.

How the data were processed

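MicroRNA levels were measured in mouse CD4 T cells on single-colour Agilent arrays labelled with Cy3, 1 array per sample. The labels give 4 groups of 2 samples: control cells (Th0), control cells with FICZ, Th17 cells, and Th17 cells with FICZ. Per the labels and the series description, the Th17 cells were naive cells differentiated for 3 days, from which IL-17 producers were isolated with beads and restimulated for 24 h with their cocktail including IL-23 at 20 ng/ml. For the control cells the sources state only that isolated CD4 T cells were restimulated with IL-2 for the same time, so differentiation and isolation of IL-17 producers also separate the Th17 groups from the controls. FICZ, a ligand of the aryl hydrocarbon receptor, was used at 100 nM. Nothing in the labels states that the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

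Per the file headers, the scans were quantified with Agilent Feature Extraction 10.7.1.1, which wrote for each of 13000 miRNA spots a raw mean intensity, a local background intensity and a processed intensity after background subtraction with spatial detrending. The deposited intensity values were not scaled between arrays. Feature Extraction also wrote a total signal per miRNA, summed over its probes. The authors deposited a further table of log2 values for 1857 probes, whose normalization method is not given in the sources used here. The medians of its columns were 7.99 and 8.02 for Th0, 7.99 and 8.02 for Th0 with FICZ, 8.06 and 7.99 for Th17, and 8.04 and 7.93 for Th17 with FICZ. Its columns ranked the probes of their own array like mean signal minus local background (Spearman rho 0.981 to 1.00 across probes), so they are log values of the same arrays and their direction is that of signal. How they were brought to nearly equal medians, and whether an offset was added, stays unknown.

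All computations started from the processed signal. Control spots and outlier spots were left out, and the remaining spots of a probe were averaged. A probe counted as detected on an array when more than 0.5 of its spots were well above background. Of 611 mouse miRNAs on the array, 330 had 2 probes and 264 had 4, and the probe with the highest mean signal stood for each miRNA. Each array was divided by the 75th percentile of its probes detected on all arrays in the fit, a floor was set at the median over arrays of the lowest scaled signal among probes well above background, and log2 was taken. A miRNA was tested when it was detected on every array of at least 1 group. Fold changes of miRNAs near the floor are understated. For a miRNA not well above background on every array of 1 group, the fold is given as a bound, the brighter group's mean log2 value against the dimmer group's mean of, per array, the higher of that array's own lowest scaled signal among probes well above background, which can lie below the common floor, and the measured value. The miRNA names are those of the array's design, and 178 entries of the lists below were matched to them.

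Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group and 5 contrasts, and Benjamini-Hochberg adjustment within each contrast at a threshold of 0.05. The contrasts were FICZ in Th17 cells, FICZ in Th0 cells, Th17 against Th0 without FICZ, Th17 against Th0 with FICZ, and the difference of the FICZ effects. The groups, this test, the lists, the rule for naming miRNAs and most alternatives were fixed before the data were examined. The planned fit used all 8 arrays, tested 147 miRNAs and took its percentile over 4 probes, because replicate 2 of Th0 with FICZ had few probes above background. Leaving that array out was among the settings fixed in advance. The fit without it tested 179 miRNAs and took the percentile over 132 probes. There detection on the single remaining array of Th0 with FICZ was enough for a miRNA to be tested. With both arrays of that group left out, 147 miRNAs were tested. Some of those that entered this way, such as miR-181d, sat at the floor with no spread in the other groups. Its results are given beside those of the planned fit, since the array stood apart in quality. Th0 with FICZ is then a single array, assumed to vary like the other groups. Residual degrees of freedom were 4 with 8 arrays and 3 with 7.

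The named miRNAs were the 8 with the largest rise and the 8 with the largest fall among those past the threshold with no overlap between the groups' arrays, or the 4 with the smallest p in a direction where fewer than 4 passed. The rule added the miR-132/212 cluster, and up to 4 members with the smallest p from each list. It was applied to the planned fit and repeated without the doubted array. The 17 lists were the miR-132/212 cluster, activation-induced and quiescence-linked T cell miRNAs, miR-17~92 and paralogs, the let-7 family, the miR-232724 clusters, the miR-15/16 family, miRNAs reported to promote or to limit Th17 cells, NF-kB feedback miRNAs, markers of myeloid, erythroid, stromal and epithelial cells, markers of endothelium, muscle and liver, GC-rich miRNAs often seen as background, and the Sfmbt2-cluster miRNAs miR-466, miR-467 and miR-669. The miR-132/212 cluster was listed from earlier work on this receptor and from the paper on this series, so it is not independent evidence. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry.

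The alternatives were normexp background correction with an offset of 50, quantile normalization, the percentile over all probes, median scaling, the total signal per miRNA, the mean of a miRNA's probes, other filters, a floor 4 times higher, an intensity trend with robust variance, fits of 2 groups only, a replicate block, array weights, the authors' log2 table, and leaving out each array in turn. Combinations of these with the doubted array left out, and a setting with no scaling, were added after seeing the data. All 8 arrays lay on 1 slide and were scanned on 1 date, so slide and scan could not act as batches. Position on the slide could, since the arrays of each group shared a row. Th0 lay in row 1, Th0 with FICZ in row 2, Th17 in row 3 and Th17 with FICZ in row 4. Row therefore cannot be told apart from group in any contrast.

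The limma fit was tested on simulated log2 values for Th17 against Th0 with 179 miRNAs, 20 simulations, and 14 miRNAs changed per fold size. The values were drawn independently around each miRNA's mean with its residual SD, and the changes were planted in both Th17 groups. The simulation had no floor, no dimmer arrays and no replicate difference shared between groups, so recovery in the real data may be lower. With 7 arrays, 41.8% of 2-fold, 65.7% of 4-fold and 83.6% of 8-fold changes were recovered, with a mean of 2.3 false calls among 29.1 calls. With 8 arrays of which 1 had failed, 0.357%, 1.07% and 16.4% were recovered. The number of arrays limits the precision of every value given. Probes for 39 viral miRNAs were left out of the tests.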

Results

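FICZ is a tryptophan-derived ligand of the aryl hydrocarbon receptor, a transcription factor that Th17 cells express at high levels. The arrays addressed which miRNAs differ between Th17 and control CD4 T cells and which respond to FICZ in each. Signal differed between groups, each of which lay in its own row of the slide. Spots well above background made up 24.1% and 22.8% of the miRNA spots on the Th0 arrays, 12% and 20.7% on the Th17 arrays, and 14% and 16.9% on the arrays of Th17 with FICZ. On Th0 with FICZ they made up 23.9% in replicate 1 and 0.508% (66 spots) in replicate 2. In that last array the negative control spots had an SD of 1106, against 7.14 to 8.79 on the other arrays, and its signals correlated at r = 0.046 to 0.286 with those of the others across 132 probes. Each comparison is therefore given with all 8 arrays and without this one, called the failed array below.

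**Figure D1:**
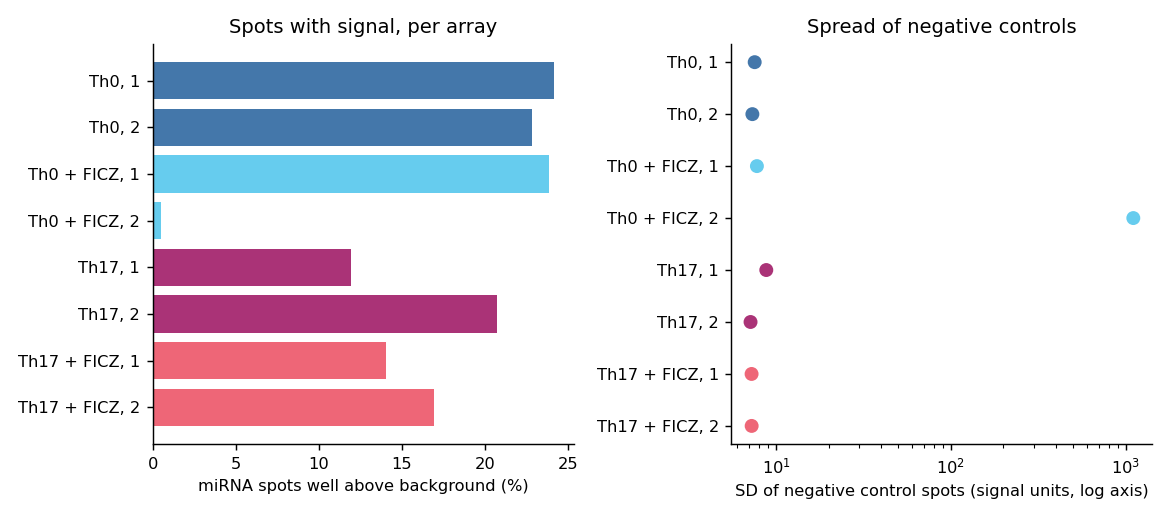
Percentage of miRNA spots well above background (bars, left) and SD of the negative control spots on a log axis (points, right) for each of the 8 arrays, coloured by group. Replicate 2 of Th0 with FICZ had 0.508% of spots above background and a negative control SD of 1106.

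The first comparison asked which miRNAs distinguish Th17 from Th0 cells. Without the failed array, miR-155, a miRNA induced on lymphocyte activation and needed for inflammatory T cell responses, rose by 2.90 on the log2 scale (SE 0.18, n = 2 arrays per group), or 7.45-fold, in Th17 cells (limma adjusted p = 0.0113). MiR-150, which is abundant in resting lymphocytes, fell by 1.45 (SE 0.14, limma adjusted p = 0.0280), and miR-693-5p rose by 2.32 (SE 0.19, limma adjusted p = 0.0223). As scaled, both Th17 arrays lay beyond both Th0 arrays for each of these miRNAs. The processed signals of miR-155 were 264 and 314 in Th0 and 412 and 1083 in Th17, and those of miR-150 were 2382 and 2776 in Th0 and 172 and 502 in Th17. Those of miR-693-5p overlapped, at 118 and 179 in Th0 and 152 and 333 in Th17. MiR-148a and miR-467b were called lower (both limma adjusted p = 0.0113), but neither was well above background on a Th17 array. There they sat at the floor with no spread, which set the size of the change and its p. Their bounds came out under 1-fold (log2 -0.26 and -0.36), so a fall is not established, and the second probe of miR-467b gave a change of 0. Each was called in 9 of 13 settings and kept its direction in 11, with values from -1.96 to 0.43 for miR-148a and from -2.02 to 0.45 for miR-467b, and with the replicate block the limma adjusted p of both was 0.0675.

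Over all 8 arrays, limma called 0 of 147 miRNAs in this comparison, with 6 at an unadjusted p under 0.05. In that fit the change of miR-155 was 2.54 (SE 0.85, limma adjusted p = 0.957) and that of miR-150 was -1.81 (SE 0.57, limma adjusted p = 0.957). The median residual SD was 0.89 log2 with 8 arrays and 0.42 without the failed array, where limma called 5 of 179 miRNAs, 2 higher and 3 lower, of which 2 rest on the floor, with 34 at an unadjusted p under 0.05. The median residual SDs of the fits cover different miRNAs and different floors. The floor was 0.309% of the 75th percentile with 8 arrays and 5.41% without the failed array, so the SDs do not isolate the spread that array added. All changes are relative to each array's 75th percentile. With no scaling, miR-155 stood at 1.21 (limma adjusted p = 0.368), and limma called 0 miRNAs higher and 44 lower. Over 14 settings without the failed array, miR-155 kept its direction in 14 and its call in 11 (limma adjusted p from 0.000264 to 0.368), and miR-150 kept its direction in 14 and its call in 7 (limma adjusted p from 0.0245 to 0.271). MiR-693-5p kept its direction in 14 settings and its call in 9, with 0.63 when not scaled (limma adjusted p = 0.591) and a limma adjusted p of 0.0917 with the replicate block. With a second array left out, miR-155, miR-148a and miR-467b were each called in 3 of 7 fits, miR-693-5p in 4 and miR-150 in 2.

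**Figure D2:**
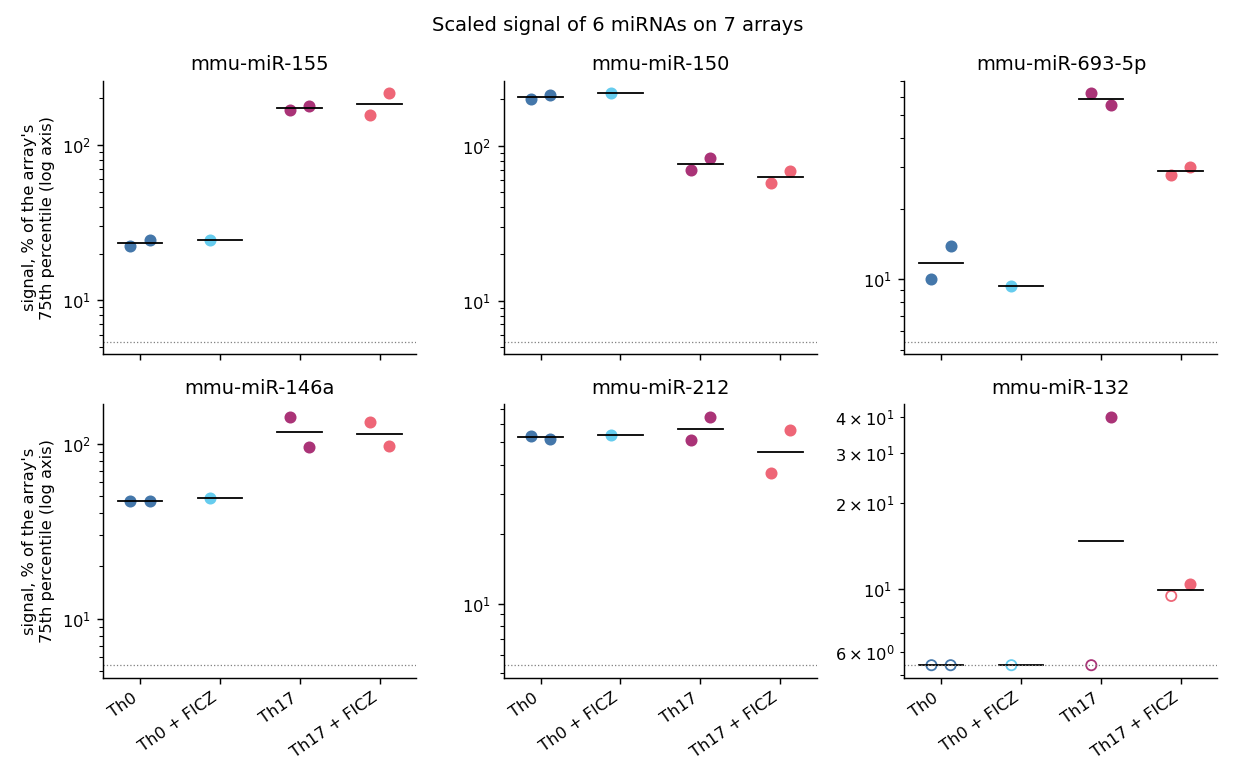
Signal of 6 miRNAs as a percentage of each array's 75th percentile (log axis) on 7 arrays, with 1 point per array, open where not well above background, a bar at each group's mean of log values and a dotted line at the floor. For miR-155 both Th17 groups lie above the 3 arrays of the Th0 groups, and for miR-150 below them.

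The activation-induced list had 10 tested members in this comparison, of which 1, miR-155, rose, 0 fell and the other members did not pass, with 4 past the threshold adjusted over the list alone. Its member miR-146a, a negative regulator of NF-kB signalling, had a change of 1.31 (SE 0.27, limma adjusted p = 0.170). MiR-210, which is induced by hypoxia, had a change of -1.88 (SE 0.44, limma adjusted p = 0.170), and miR-96 one of -0.98. MiR-21, the brightest of the named members with processed signals of 15714 and 16938 in Th0, had a change of -0.38 (SE 0.28, limma adjusted p = 0.602). Of 14 quiescence-linked miRNAs, 1, miR-150, fell and 0 rose. MiR-342-3p in that list had a change of -0.63 and miR-29b one of 0.46, neither past the threshold. The 3 NF-kB feedback miRNAs, miR-155, miR-146a and miR-21, had a median change of 1.31 (camera in limma, adjusted p = 0.0915), with 2 past the threshold adjusted over the list alone. Of 6 miRNAs reported to promote Th17 cells, miR-155 rose and 0 fell. Of 9 reported to limit them, 0 passed, 8 had values below 0 and miR-146a was above. As lists, the activation-induced (camera in limma, adjusted p = 0.971), quiescence-linked (0.143), Th17-promoting (0.620) and Th17-limiting (0.143) miRNAs did not pass.

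The let-7 family, which is abundant in differentiated cells, was lower in Th17 cells, with 7 of 8 members below 0, a median change of -0.85 and none past the threshold alone (camera in limma, adjusted p = 0.0373 without the failed array). That call was lost with an estimated correlation (limma camera, adjusted p = 0.809) and with quantile normalization, and over 8 arrays the list had a median of -1.21 (camera in limma, adjusted p = 0.0720). The size depended on the dimmer Th17 replicate 1. The list's median processed signal was 92.3 there and 394 on replicate 2. In fits that kept the failed array, the let-7 family had a median of -0.66 without Th17 replicate 1 and -1.76 without Th17 replicate 2. Those fits took their scale over the few probes detected on the failed array, so their scale and floor differ from those behind the median of -0.85. The member mmu-let-7a stood at -0.92 (SE 0.57), with log2 values of -0.89 and 0.10 in Th17 and 0.54 and 0.50 in Th0, let-7i at -0.91 (SE 0.34) and miR-98 at 0.25 (SE 0.40). The miR-15/16 family had 4 of 5 values below 0, with miR-16 at -1.15 and miR-15a at -1.10 (list median -0.96, camera in limma, adjusted p = 0.0574). The miR-17~92 list had 10 of 12 values below 0 (median -0.41, camera in limma, adjusted p = 0.0915), and the miR-232724 list 4 of 5 (median -0.20, camera in limma, adjusted p = 0.620). Among 26 Sfmbt2-cluster miRNAs, 17 had values above 0 and 8 below (median 0.49, camera in limma, adjusted p = 0.0373 without the failed array and 0.00742 over 8 arrays). With an estimated correlation the list's limma camera adjusted p was 0.809 without the failed array and 0.716 over 8. With no scaling the list's median was -0.91.

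**Figure D3:**
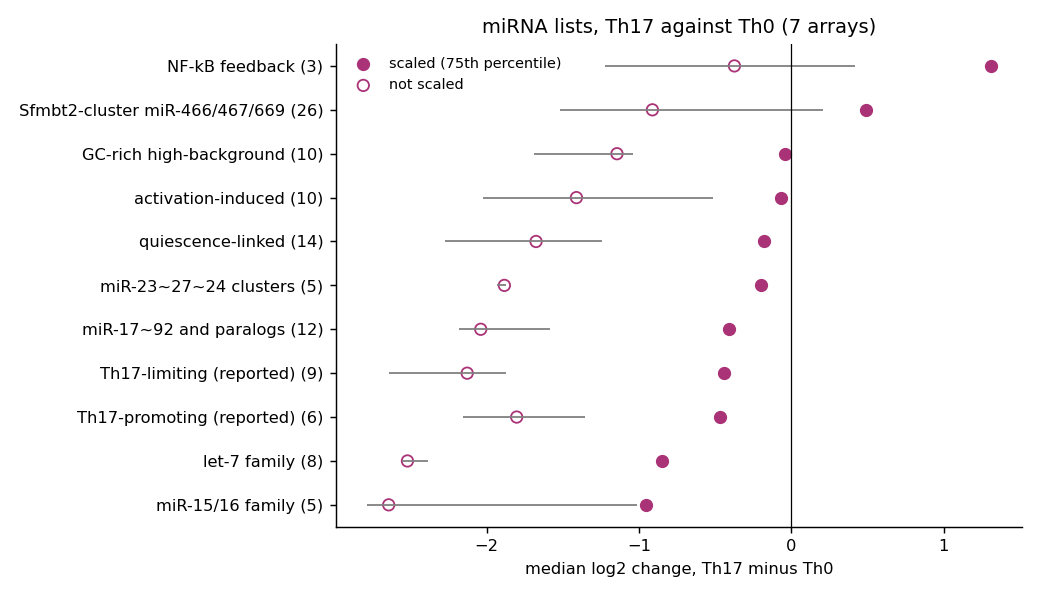
Median log2 change, Th17 minus Th0, of 11 miRNA lists on 7 arrays, scaled to the 75th percentile (filled) or not scaled (open, with a grey line between the quartiles of the unscaled changes), with the number of tested members in brackets. The let-7 list has a median of -0.85 scaled and -2.52 unscaled, and the Sfmbt2-cluster list 0.49 scaled and -0.91 unscaled.

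In the presence of FICZ the comparison of Th17 with Th0 cells rests on 1 array of Th0 with FICZ once the failed array is left out. There miR-155 rose by 2.91 (SE 0.23) and miR-150 fell by 1.79 (SE 0.17), both with a limma adjusted p of 0.0337. MiR-148a and miR-467b were called lower (both limma adjusted p = 0.0337), but they were again at the floor on the Th17 arrays, with bounds under 1-fold (log2 -0.22 and -0.14), so a fall is not established. MiR-693-5p had a change of 1.63 (SE 0.24, limma adjusted p = 0.102). As scaled, miR-574-3p was at least 20.3-fold higher in Th17 with FICZ, miR-466g at least 19.8-fold, miR-466i at least 19.2-fold and miR-467g at least 10.6-fold. The comparison was with a single array where these miRNAs were not well above background, and none of them was called. In the fit, whose common floor is higher, their log2 changes were 3.50, 3.47, 3.42 and 2.56. Not scaled, their mean processed signals were 234, 225, 220 and 132 in Th17 with FICZ, against 21.58, 20.45, 27.97 and 9.1. The bounds therefore depend on the scaling. MiR-466g, miR-466i and miR-467g belong to the Sfmbt2-cluster list. For its scaled rise without FICZ, non-specific signal divided by a lower scale could not be told apart (below). In the 2 Th0 arrays without FICZ, miR-574-3p, miR-466g and miR-466i were well above background.

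Over all 8 arrays limma called 0 of 147 miRNAs in this comparison, with 14 at an unadjusted p under 0.05, and without the failed array 4 of 179, with 32. All 4 were among the 5 called without FICZ, and that overlap was not tested. MiR-155 kept its call in 10 of 14 settings and miR-150 in 4, both with their direction in 14, and miR-148a kept its call in 9 of 13 and miR-467b in 8, both with their direction in 11. With a second array left out, miR-155 was called in 2 of 6 fits and miR-150, miR-148a and miR-467b in 0. With the replicate block all 4 calls were lost (limma adjusted p from 0.0898 to 0.161). Of the lists, 0 of 11 passed (smallest camera adjusted p in limma 0.145 over 8 arrays and 0.0522 without the failed array). The let-7 family had 8 of 8 members below 0 without that array, with a median of -1.07, and over 8 arrays 3 below and 5 above, with a median of 0.26.

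FICZ in Th17 cells is the comparison that the title of the series points to. Neither with 8 arrays nor with 7 did a miRNA pass. MiR-212, which with miR-132 forms a cluster reported to respond to this receptor, had a change of -0.33 (SE 0.27, n = 2 arrays per group, limma adjusted p = 1). MiR-132 was well above background on replicate 2 of Th17 and replicate 2 of Th17 with FICZ and on no other array, and was not tested. Its processed signals were 12.7 and 243 in Th17, 20.6 and 68.0 in Th17 with FICZ, and 0.7 and 11.4 in Th0. MiR-693-5p had the smallest p, with a change of -1.01 (SE 0.19, limma unadjusted p = 0.00856, adjusted p = 1) and, as scaled, both FICZ arrays below both Th17 arrays. Its processed signals overlapped, with a mean of 242.5 (SD 128.4) in Th17 and 128.4 (SD 96.1) in Th17 with FICZ. MiR-155 stood at 0.07 (SE 0.18), miR-150 at -0.27 (SE 0.14) and let-7b at -0.44 (SE 0.19).

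For FICZ in Th17 cells limma called 0 of 147 miRNAs over 8 arrays, with 0 at an unadjusted p under 0.05, and 0 of 179 without the failed array, with 1. The 95% interval of a change, not adjusted for the number of miRNAs, had a median half-width of 1.12 log2, or 2.17-fold. It lay within 1 log2 unit of 0 for 67 of 179 miRNAs, so for most a change of 1 log2 unit was not excluded. Some miRNAs, such as miR-148a, miR-467b, miR-363 and miR-195, sat at the floor with no spread in both Th17 groups. Their change of 0 was set by the floor, so their intervals exclude no change. How many of the 67 were of this kind was not counted. A call after adjustment needed a change larger than the miRNA's own half-width. The replicate difference shared by both Th17 groups counted as spread in these intervals. Of 11 lists, 0 passed. The smallest camera adjusted p in limma was 0.624 over 8 arrays and 0.210 without the failed array, where the let-7 family had 8 of 8 members below 0 and a median of -0.18.

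FICZ in Th0 cells gave no called miRNA either. MiR-212 had a change of 0.03 (SE 0.32), miR-155 one of 0.06 and miR-150 one of 0.07 with 1 FICZ array against 2, all with a limma adjusted p of 1. MiR-92a, from the miR-17~92 cluster, had the smallest p with a change of 0.19 (SE 0.07, limma unadjusted p = 0.0541). Limma called 0 of 147 miRNAs over 8 arrays and 0 of 179 without the failed array, with 0 at an unadjusted p under 0.05 in both. Over 8 arrays the let-7 family was the 1 list that passed, with a median of -1.49 (camera in limma, adjusted p = 0.00867). Its median without the failed array was 0.05 (camera in limma, adjusted p = 0.875), and with an estimated correlation over 8 arrays the limma camera adjusted p was 0.759. The median half-width of the 95% intervals was 1.37 log2, or 2.58-fold, without the failed array.

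The FICZ effect in Th17 cells was last set against that in Th0 cells. The difference was -0.36 for miR-212 (SE 0.42) and -0.68 for miR-693-5p (SE 0.31) without the failed array, both with a limma adjusted p of 1. Limma called 0 miRNAs with 8 arrays and 0 with 7, with 0 at an unadjusted p under 0.05 in both, so no effect of FICZ was shown to differ between the cell populations. Of 11 lists, 0 passed (smallest camera adjusted p in limma 0.0524 over 8 arrays and 0.784 without the failed array). Across miRNAs, which are not independent replicates, the changes with FICZ in Th17 and in Th0 cells correlated at r = -0.0218 (95% interval -0.183 to 0.141, 147 miRNAs, Spearman rho -0.0144) over 8 arrays and at r = -0.252 (-0.385 to -0.110, 179 miRNAs, Spearman rho -0.286) without the failed array, where quantile normalization gave r = -0.222 with a Spearman rho of -0.011.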

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

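Of the tests below, the one on the failed array and the one on slide column were chosen only after the result was seen, and the others were written down before, that on signal near background when the correlation over all tested miRNAs had already been seen. Probes for viral miRNAs, which the comparisons do not use, gave 5 signals above the highest Th0 value. Feature Extraction's total signal of mcmv-miR-M23-1-5p on Th17 replicate 1 was 13722, against a highest Th0 value of 323, but its 20 spots on that array had a median processed signal of 46.5 and a highest of 78.2, so the total was not borne out by the spots. That of mcmv-miR-m22-1 on Th0 with FICZ replicate 1 was 348, against 0.1 in Th0, where Feature Extraction did not detect it, but its mean processed signal there was 28.6, against 30.2 and 28.4 in Th0. MiRNA mghv-miR-M1-6 had 129 on Th0 with FICZ replicate 1 and 117 on Th17 replicate 2, against 107 in Th0, with mean processed signals of 105 and 27.6 against 103 and 90.7. MiRNA mghv-miR-M1-8 had 144 on Th0 with FICZ replicate 1, against 133, with 26.1 against 31.1 and 50.2. No cause was tested for these 5 signals. Of 39 viral miRNAs, 4 and 5 were well above background on the Th0 arrays and 5 on Th0 with FICZ replicate 1. On the Th17 arrays 2 and 3 were, and on those of Th17 with FICZ 2 and 3. The probe of mcmv-miR-M23-1-5p had mean processed signals of 311 and 349 in Th0, where miR-155 had a mean of 289. If this was non-specific signal, which was not tested, the detection rule passed such signal at the level of named miRNAs.

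The absence of calls between Th17 and Th0 over 8 arrays was set against the high non-specific signal of Th0_FICZ replicate 2. Without that array limma called 5 miRNAs, and without any other single array at most 2, which is what this explanation needs. Of the 5, miR-148a and miR-467b rest on the floor. The 2 came without Th0 with FICZ replicate 1, where the failed array was alone in its group and added no spread. Over 8 arrays limma called 0 with median, quantile or all-probe scaling, with no filter, and in a fit of the Th17 and Th0 arrays alone, which had fewer degrees of freedom, with 7, 7, 9, 10 and 38 at an unadjusted p under 0.05. With array weights, at the planned scale and with the same 147 miRNAs, limma called 4, and both arrays of Th0 with FICZ had a weight of 0.138, against 0.962 to 5.35 on the others. The failed array may account for the absence of calls in part through the spread it added. The share of the scale, the floor and the filter stays open, and what made the array fail was not tested.

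The higher scaled values of the Sfmbt2-cluster miRNAs in Th17 cells could come from non-specific signal divided by a lower scale, since the Th17 arrays were dimmer. Unscaled, the list's median change was -0.91, with quartiles from -1.52 to 0.21, against -1.31 for the other miRNAs. This lay outside both values written down beforehand, within 0.5 of 0 for that cause and above 0.5 without it, and the quartiles lay on both sides of 0, so the cause cannot be told apart from a change in these miRNAs relative to the rest. For the GC-rich miRNAs the same explanation was written down, but their scaled median was -0.04, so there was no rise to explain. Their unscaled median of -1.15 (quartiles -1.69 to -1.04) lay far from the value near 0 written down for it. For both lists that value assumes non-specific signal that does not fall on dimmer arrays, which was not tested, so the test cannot count against this cause. A biological difference between Th17 and Th0 cells stays open and untested.

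Replicates 1 and 2 of Th17 differed in much the same way as replicates 1 and 2 of Th17 with FICZ (r = 0.748 across 179 miRNAs). Slide column, which the replicate number follows, would give the same differences in Th0, where the correlation with Th17 was -0.102 (95% interval -0.245 to 0.0454). Signal near background on the dimmer arrays would weaken the relation among well-measured miRNAs, but over the 71 miRNAs detected on all 7 arrays it was 0.856 (0.778 to 0.908). Non-specific signal above background, divided by the lower scale of a dimmer array, would pass that filter, so the test does not reach it. That stays open and was not tested. So does a difference between cell preparations or in RNA or label yield that the 2 Th17 groups may share. No biological explanation is given by the design.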

How the results depend on the processing

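Tests named below as without the failed array (Th0 with FICZ replicate 2) in combination with another choice, with a second array left out or with no scaling were chosen only after the result was seen. Over 8 arrays each of the 5 counts was 0 under every scaling, background, filter, floor and test setting that ran, except with array weights, where limma called 4 miRNAs in Th17 against Th0 (3 higher, 1 lower). With the replicate block limma called 0 miRNAs in each of the 5 contrasts over 8 arrays. The replicate block without the failed array left 2 in Th17 against Th0, miR-155 and miR-150, and 0 with FICZ. The replicate numbers were not shown to pair the samples across all groups. Differences between replicates correlated at -0.102 between Th0 and Th17 and at -0.401 between Th0 and Th17 with FICZ. Between the Th17 groups they correlated at 0.748. Arrays of the same replicate number correlated at 0.9625 and 0.9777 between these groups, against 0.919 and 0.829 within them. The fit without a block counted that shared difference as spread for FICZ in Th17. The block set 1 replicate effect over all groups, Th0 included. A fit pairing only the Th17 groups was not run. Filtering to miRNAs detected on all 8 arrays left 3 miRNAs and was not run, and a slide block was not run because there was 1 slide.

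Leaving out single arrays, or the failed array with a second, gave from 0 to 1 calls for FICZ in Th17, 0 to 76 for FICZ in Th0, 0 to 12 for Th17 against Th0, 0 to 68 for Th17 against Th0 with FICZ, and 0 to 64 for the difference of the FICZ effects. The values of 76, 68 and 64 came without Th0 with FICZ replicate 1, which leaves the failed array alone in its group, and Th17 against Th0 then had 2. Without the failed array the counts for Th17 against Th0 and the same with FICZ were 5 and 4. With a further choice changed they were 5 and 1 with normexp, 9 and 10 with quantile normalization, 2 and 10 with the percentile over all probes, 6 and 4 with median scaling, 44 and 44 with no scaling, 18 and 19 with the total signal, 8 and 5 with the mean of probes, 2 and 3 for miRNAs detected on all 7 arrays, 2 and 3 with no filter, 6 and 5 with a floor 4 times higher, 6 and 6 with trend and robust variance, and 1 and 12 with the authors' log2 values. For FICZ in Th0 there were 3 with no scaling, 5 with the total signal and 1 with no filter, and for the difference of the FICZ effects 5 with the total signal and 1 with no filter. Splits moved with scaling: against 2 higher and 3 lower in Th17 against Th0, quantile normalization gave 2 and 7, all probes 0 and 2, and no scaling 0 and 44. The median change of all miRNAs was then -0.22, -0.21 and -1.24, against 0 as scaled, and it was -0.15 with median scaling and 0.45 with normexp. With no filter, the call for FICZ in Th0 and that for the difference was miR-181d, which was also called in Th17 against Th0 with FICZ. It sat at the floor of -4.21 log2 with no spread in the other groups and at -4.10 on the single array of Th0 with FICZ. Its calls therefore rest on the floor. Otherwise the cause was not tested, except that filters change which miRNAs are tested.

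Lists past the threshold depended on the set test. For FICZ in Th0 there was 1 over 8 arrays, and 0 with an estimated correlation, fry, quantile normalization or the percentile over all probes, and 5 with normexp. There were 0 without the failed array with an estimated correlation, fry, normexp, quantile normalization, all probes or no scaling. For Th17 against Th0 there was 1 over 8 arrays, and 0 with an estimated correlation or fry and 4 with normexp. Without the failed array there were 2, and 0 with an estimated correlation, quantile normalization, no scaling or miRNAs detected on all 7, and 7 with normexp. For Th17 against Th0 with FICZ normexp, quantile normalization and all probes each gave 1 over 8 arrays, and fry gave 1, the replicate block 2 and normexp 4 without the failed array. For FICZ in Th17 all probes and no scaling each gave 1 without the failed array, and for the difference of the FICZ effects normexp gave 6 over 8 arrays and the replicate block 1 without the failed array. Leaving out arrays gave 0 to 7 lists for FICZ in Th17, 0 to 1 for FICZ in Th0, 0 to 6 for Th17 against Th0, 0 to 2 with FICZ, and 0 to 3 for the difference.

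Some list medians and single miRNAs turned. The let-7 median for FICZ in Th0 was -1.49 over 8 arrays, and without the failed array 0.0521 by camera, 0.0521 with an estimated correlation and with fry, 0.295 with the replicate block, 0.0212 with normexp, 0.0229 for miRNAs detected on all 7 arrays and -0.0914 with no scaling. It ranged from -2.74 to 0.0521 as arrays were left out. For the Sfmbt2-cluster miRNAs that median was 0.69 over 8 arrays and -0.132 for miRNAs detected on all 7. For Th17 against Th0 with FICZ the let-7 median was 0.26 over 8 arrays, and -1.34 with the replicate block and -0.775 with normexp without the failed array, and that of the miRNAs reported to limit Th17 cells was -0.354 with normexp. For FICZ in Th17 the medians ranged, as arrays were left out, from -0.513 to 0.404 for the quiescence-linked list, -0.486 to 0.576 for miR-17~92, -0.498 to 0.621 for miR-232724, -0.589 to 0.528 for the Th17-limiting list and -0.318 to 0.582 for the Sfmbt2-cluster list. As arrays were left out, mmu-miR-21* for FICZ in Th0 ranged from -0.27 to 1.18, and for Th17 against Th0 with FICZ mmu-miR-210 ranged from -2.46 to 2.43, mmu-let-7c from -1.48 to 1.46 and mmu-miR-301a from -1.51 to 1.72. These ranges, and that of the let-7 median for FICZ in Th0, include the fit without Th0 with FICZ replicate 1. There the failed array stood alone for its group, so the ranges are not those of the usable arrays alone. Without the failed array and with no scaling, mmu-miR-1224 was -1.91 and mmu-miR-671-5p -0.97 in that comparison, mmu-miR-467a* was 2.86 for miRNAs detected on all 7, and mmu-miR-92a was 0.25 in Th17 against Th0 with the mean of probes. The correlation of the FICZ effects was 0.248 with quantile normalization, and without the failed array -0.252, -0.222 with quantile normalization (Spearman rho -0.011) and -0.304 for miRNAs detected on all 7. The causes were not tested.

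Depth on these arrays is signal over background, and the Th17 arrays were dimmer than those of Th0. The floor lies on the scaled value, so low miRNAs sat at it on arrays of either cell population. Folds of miRNAs not well above background in a group are bounds, with none given where the bound is under 1-fold.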

Other observations

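Markers of other cell types were measured on the same arrays. The myeloid marker miR-223 and the markers of erythroid and epithelial cells, 1, 3 and 8 miRNAs on the array, had 0 members tested and 0 above background on every array. Of 11 stromal miRNAs 2 were tested, both arms of miR-140, with changes between Th17 and Th0 of -0.79 (SE 0.56) and -0.26 (SE 0.11) without the failed array. Of 9 markers of endothelium, muscle and liver 2 were tested, miR-206 at -0.02 and miR-122, which was not well above background in either group. None of these passed limma's test, and the cluster of miR-132 and miR-212, with 1 tested member, was too small to test as a list.

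The GC-rich miRNAs, which often carry background on such arrays, had 10 tested members, of which 0 passed in Th17 against Th0 without the failed array. Their median change was -0.04 (camera in limma, adjusted p = 0.971), with miR-494 at 0.58 (SE 0.16) and miR-188-5p at -1.05 (SE 0.64). MiR-34a, a miRNA under p53 control, stood at 1.36 (SE 0.23, limma adjusted p = 0.134).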
